A study of Mus musculus with 2 samples.

How the data were processed

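RNA sequencing had been carried out on total RNA of brain endothelial cells from C57BL/6 mouse embryos at embryonic day 13, in 1 library labelled WT and 1 library labelled ECKO. Per the labels, the mice carried a floxed Rnf20 gene with or without deletion by Tie2-driven Cre, a driver active in endothelial and blood cells. The series text speaks of triplicates, whereas 2 libraries, 1 per genotype, were analysed here. How the endothelial cells were isolated and which exons were deleted are not given in the sources used here.

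Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 were used, with no role or order stated, and the build was mm9. The gene positions in the deposited table lie on GRCm38 instead. Of the 18976 gene identifiers, 18929 were found in GENCODE M21, 16983 with the identical start and end and 18928 overlapping the same gene. Coordinates are given as in the deposited table and read as GRCm38.

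The deposited table holds raw counts per gene for each library, per the file headers, and lists genes with a summed count of at least 2. The authors' normalized values are CPM, that is counts scaled to a fixed library total. Every CPM value of a gene with counts equalled the count over a library total, within a relative difference of 1e-06, and a count of 0 had been given the value of 0.5 counts. The library totals behind the CPM exceeded the sums of the listed genes by 1974 counts (WT) and 2143 counts (ECKO). The authors' deposited fold change is the ratio of the ECKO to the WT value, and the authors' log2 fold change is its logarithm. The deposited p-values and adjusted p-values come from 2 libraries without replicates, and the test behind them is not given in the sources used here. No column of per-sample values was left unused.

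Total counts were 16076560 (WT) and 17128789 (ECKO). Libraries were scaled with TMM factors of 1.04 (WT) and 0.963 (ECKO) from edgeR 4.0.16 in R 4.3.3. A count of 0 was set to a floor of 3 counts, a CPM of 0.180 (WT) or 0.182 (ECKO) on the scaled libraries. A ratio against 0 is thus a bound set by this floor, and the gene's 95% interval, described next, reaches closer to 0. Each log2 ratio of the library labelled ECKO to that labelled WT carries an exact Clopper-Pearson 95% interval from the 2 counts. Sequencing reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

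With 1 library per group no test across libraries was made and no p-value was computed. A gene passed the size rule when its summed count was at least 50, its absolute log2 ratio at least 1 and its whole interval on 1 side of 0. Before the data were examined, 30 gene lists, the size rule and the rule for named genes had been fixed. For each list with at least 5 tested genes, the median log2 ratio was placed among the medians of 10000 random lists of like size matched on mean expression in 20 bins. This percentile describes these libraries only. A bootstrap interval of the median was taken over 2000 draws of the genes. Named genes were Rnf20, the 12 higher and 12 lower genes whose interval bound nearest 0 lay farthest from 0 (predicted and clone-named genes excepted), and up to 2 members past the size rule per direction in each list, or the 2 with the highest summed count where none passed. All members of the list of H2B monoubiquitination genes and of the list of sex-linked genes could be named. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule would name are not reported here.

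Transcript lengths came from GENCODE M21. The longest transcript was used with 10 expression and 10 length bins, and the APPRIS principal transcript with 5 expression and 20 length bins. Alternatives covered other scalings (total gene counts, upper quartile, size factors of DESeq2 1.42.0), other count and size thresholds, the authors' CPM with pseudocounts of 1 and 0.1, and, added after the data had been seen, removal of the length trend (lowess, statsmodels 0.14.6), a summed count of at least 5000 and omission of the sex chromosomes. Ratios and intervals were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

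The size rule was tested on simulated counts of these 2 libraries with counting error only. It recovered 99% of 100 genes changed 3-fold and 100% of 100 genes changed 6-fold, and 0.114% of 13168 unchanged genes passed. The intervals held the true ratio for 95.4% of 13368 genes. A simulated list of 30 genes shifted by 0.5 in log2 lay at percentile 100, and the unshifted list at percentile 49.0. The real ratios spread far more than counting error (robust SD 1.77 against 0.35 at summed counts of 50 to 100). These simulated rates and percentiles therefore check the calculation and do not carry over to the real calls and lists.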

Results

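Gene expression was compared between brain endothelial cells of mouse embryos at embryonic day 13 from 1 library labelled WT, from mice with the floxed Rnf20 gene, and 1 library labelled ECKO, from mice in which Rnf20 was to be deleted by Tie2-driven Cre. Which endothelial genes depend on Rnf20 at this stage cannot be told from it, since each genotype has 1 library and the 2 libraries differ in embryo sex. The libraries held 16076560 counts (WT) and 17128789 counts (ECKO), over 17439 and 17783 detected genes. The 10 most abundant genes took 5.78% and 5.70% of the counts, and mitochondrially encoded genes 2.32% and 1.74%. The difference has no replicate check, and all intervals are 95% counting intervals of a ratio between 2 libraries.

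Rnf20 was not lower in the library labelled ECKO. Rnf20 (ENSMUSG00000028309, chromosome 4, 49632006 to 49656887, GRCm38) encodes a ubiquitin ligase that, together with Rnf40, places ubiquitin on histone H2B. It had 1496 counts in the library labelled ECKO and 1195 in the library labelled WT, a log2 ratio of 0.34 (interval 0.23 to 0.45). Among 1165 protein-coding genes with 0.8 to 1.25 times its summed count, this ratio lay at percentile 73.3. The deleted exons are not given, and the counts cover whole genes, so reads from remaining exons are included. Because the level of Rnf20 does not show which library carries the deletion, the libraries are named by their labels, and every direction given here rests on them. Of the 20 tested genes of H2B monoubiquitination, Wac, an adaptor of the Rnf20/Rnf40 ligase, was 2.87-fold lower (log2 -1.52, interval -1.72 to -1.32), and no other member passed the size rule. Rnf40 had a log2 ratio of -0.03 (interval -0.19 to 0.14), and the list median of 0.10 lay at percentile 67.1 of random lists.

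Across 13343 tested genes, 1099 were higher and 1701 lower in the library labelled ECKO by the size rule, 2800 in all. Most of these were of low abundance. Among protein-coding genes, the rule was passed by 56.7% of those with a summed count of 50 to 100, and by 2.24% of those with 5000 to 20000. The spread of log2 ratios was 1.77 (robust SD) at 50 to 100 counts, against 0.35 from counting, and 0.34 at 5000 to 20000 counts, against 0.03 from counting. Counts of 0 in either library were found for 192 tested genes, 86 of them at 0 in the library labelled WT and 106 at 0 in the library labelled ECKO.

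**Figure D1:**
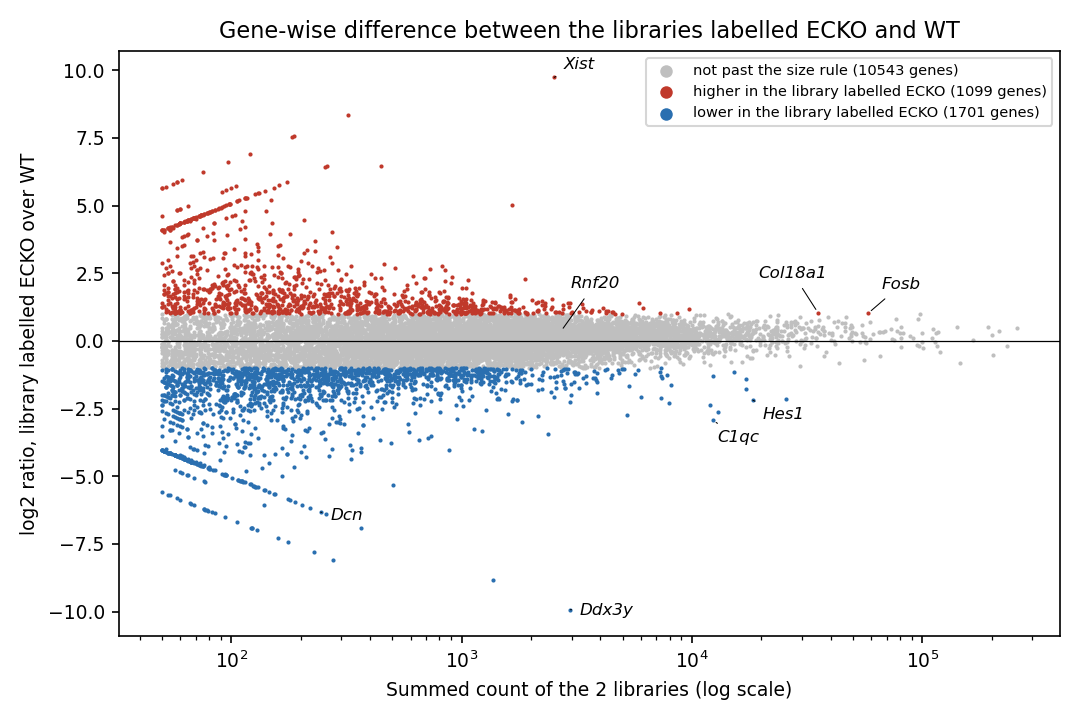
Log2 ratio of the library labelled ECKO to that labelled WT (vertical axis) against the summed count of both (horizontal axis, log scale) for 13343 genes, 1 point per gene. The 1099 higher and 1701 lower genes crowd at low counts, and the slanted rows of points are genes with very few counts in 1 library, those at 0 being set to the floor of 3 counts.

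The genes whose counting intervals lay farthest from 0 were nearly absent from 1 library. Their summed counts were mostly low, where the spread of ratios far exceeds counting error, so these intervals do not show that the differences would recur. Apart from Xist, those higher in the library labelled ECKO included Lox, which cross-links collagen (132 against 0 counts, at least 44.6-fold), the potassium channel regulator Abcc8 (161 against 0, at least 54.3-fold), the chemokine receptor Cxcr2 (130 against 0, at least 43.9-fold) and Serpina3g (126 against 0, at least 42.5-fold). The cartilage collagen gene Col9a2 had 319 against 1 counts (log2 8.34, interval 5.85 to 13.64), Kcnk6 185 against 1 and the protease gene Adamts12 182 against 1. Tmem26 (116 counts), Arhgef37 (114) and the protocadherin Pcdhga9 (114) were also at 0 in the library labelled WT. Xlr3b had 260 against 0 counts, but belongs to a family of near-identical X-linked copies, and its count is uncertain, as is that of Pcdhga9, which shares exons with its cluster. On the lower side, beyond the Y-linked genes, were Dcn, a proteoglycan of fibroblasts (0 against 244, at least 80.3-fold), the mast cell protease Tpsb2 (0 against 220, at least 72.4-fold, uncertain through its close paralog), Gspt2 (0 against 203), Gca (0 against 188), the protease Ctse (1 against 276, log2 -8.09, interval -13.40 to -5.60), the integrin Itga8 (0 against 179), the thiamine transporter Slc19a2 (0 against 176) and Disp3 (0 against 154).

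Few general endothelial identity genes passed the size rule. Of 35 tested pan-endothelial genes, 1 passed the size rule, Rasip1, a regulator of vessel lumen formation, which was 2.38-fold lower in the library labelled ECKO. When scaled to total gene counts, Flt1, named after its values were seen (10144 against 19378 counts, log2 -0.92 in the main analysis), passed as lower too, here and among the tip cell genes below. The list median was 0.32 (bootstrap interval 0.13 to 0.41), at percentile 96.2 of random lists of like expression, and at 96.4 and 99.1 when these were matched on the longest or the principal transcript as well. Brain barrier and Wnt response genes had a median of 0.28 (percentile 94.3) over 35 genes. Foxq1, a forkhead factor of brain endothelium, was 2.84-fold lower, and Reck, a coreceptor component for Wnt7 signals, 2.91-fold lower, while Foxl2 was 2.31-fold higher at 48 against 21 counts. Among 23 tip cell and VEGF genes (median 0.32, percentile 95.4), the semaphorin and VEGF coreceptor Nrp2 was 2.71-fold higher and Pdgfb, which recruits pericytes, 2.03-fold lower.

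Of 23 tested Notch pathway genes, 4 were lower in the library labelled ECKO and none was higher. Of all 13343 tested genes, 1701 were lower and 1099 higher. Hes1, a transcriptional repressor downstream of Notch, had 3268 against 15116 counts (4.57-fold lower, log2 -2.19, interval -2.25 to -2.14), and the ligand Dll3 was 6.37-fold lower at 20 against 129 counts. The list as a whole had 12 genes above 0 and 11 below, with a median of 0.01 at percentile 39.1. The other lower genes, named after their values were seen, were Hes5, which is also in the list of neural precursor markers (median -1.25), and Nrarp (log2 -1.04). From which cells the reads of these 4 genes came cannot be told from the counts, so they are no measure of endothelial Notch activity. Of 16 arterial genes, the gap junction gene Gja5 (143 against 7 counts, 20.7-fold) and the chemokine Cxcl12 (2.26-fold) were higher and none was lower (median 0.12, percentile 61.4). Among 11 venous and lymphatic genes (median -0.09, percentile 29.2), Nrp2 was higher, and Ackr1 (3.29-fold) and Lyve1 (2.10-fold) were lower.

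TGF-beta and matrix genes past the size rule went both ways in the library labelled ECKO. Of 28 genes of endothelial-to-mesenchymal transition and TGF-beta signalling, 4 were higher and 2 lower. Tgfb3 was 6.89-fold higher (102 against 15 counts) and Tgfb1 3.84-fold higher (273 against 72), whereas the inhibitory Smad6 was 3.08-fold and the smooth muscle actin Acta2 2.87-fold lower. Tgfb2 and Bmp2, chosen after their values were seen, had log2 ratios of -0.32 and -0.86. The list median of 0.21 lay at percentile 85.4. Of 31 extracellular matrix and basement membrane genes, 4 were higher, including Tnc (136 against 5 counts, 27.5-fold) and Lama1 (2.68-fold), and 1 was lower, the membrane-bound protease Mmp14 (2.62-fold). The other higher genes, Col18a1 and Col15a1 (the latter named after its values were seen), did not pass when scaled to total gene counts, which leaves 2 higher. The list median of 0.36 lay at percentile 99.1, and at 94.6 and 93.7 when random lists were matched on the longest or the principal transcript as well. Of 36 secreted factors known to act on neural precursors, 3 were higher and 6 lower (median -0.06, percentile 8.47). Spp1 (osteopontin) was 3.39-fold lower at 3857 against 13251 counts and Ccl2 2.24-fold lower, while Tgfb1 and Sema3g (2.31-fold) were higher.

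Of 22 inflammation genes, 4 were lower and 1 higher in the library labelled ECKO, with 12 below 0 and 10 above. Their median of -0.30 (bootstrap interval -0.56 to 0.35) lay at percentile 0.28, or at 3.10 and 5.12 with matching on the longest or the principal transcript, and was -0.11 with the length trend removed. The chemokines Cxcl10 (3.33-fold) and Ccl2 were lower, and Birc3, an apoptosis inhibitor, was higher (1165 against 537 counts). Interferon response genes had a median of -0.09 (percentile 34.3, 24 genes), with Cxcl10 lower and Rsad2 2.13-fold higher, though not past the rule when scaled to total gene counts (log2 0.98). Of 37 cell cycle genes, Ccnb2 (2.77-fold) and Ccnd2 (2.38-fold, 2290 against 5508 counts) were lower, and the median was 0.09 (percentile 40.9). Among 26 p53 targets and CDK inhibitors, 3 were higher, including Perp (4.72-fold) and Cdkn1b (2.02-fold), of which only Perp passed when scaled to total gene counts (Cdkn1b log2 0.90), and 4 lower, including Cdkn1c (9.50-fold, 16 against 154 counts) and Phlda3 (4.50-fold), around a median of -0.05 (percentile 33.2).

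Oxidative phosphorylation genes were lower in the library labelled ECKO. Over 36 genes the median was -0.58 (bootstrap interval -0.78 to -0.12), below every random list of like expression (percentile 0), and 7 genes were lower, among them the complex I genes Ndufa2 (3.08-fold) and Ndufa6 (2.34-fold), with none higher. With the trend over transcript length removed the median was -0.28. Genes with short transcripts were lower in general. The 10% of protein-coding genes with the shortest transcripts (231 to 1503 nt) had a median of -0.40, and the 10% with the longest a median of 0.11. Glycolysis and hypoxia genes had a median of 0.06 (percentile 27.7, 31 genes) with 1 member past the rule, Gapdh (2.01-fold higher, but not past the rule when scaled to total gene counts, log2 0.90), whose counts are uncertain because of its many pseudogenes. The unfolded protein and stress response list had a median of 0.14 (percentile 50.5, 28 genes), with Hyou1 2.42-fold higher, and Slc7a11 and Cebpb lower at 8 against 52 and 8 against 50 counts. Immediate early genes had a median of 0.16 (percentile 37.3, 27 genes), with Fosb 2.02-fold higher at 38782 against 19408 counts (log2 1.02, but 0.91 when scaled to total gene counts, which ends the call) and Rhob 2.27-fold lower. Cholesterol genes had a median of -0.07 (percentile 14.3, 28 genes), with Fdps among the members that were lower (2.21-fold).

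**Figure D2:**
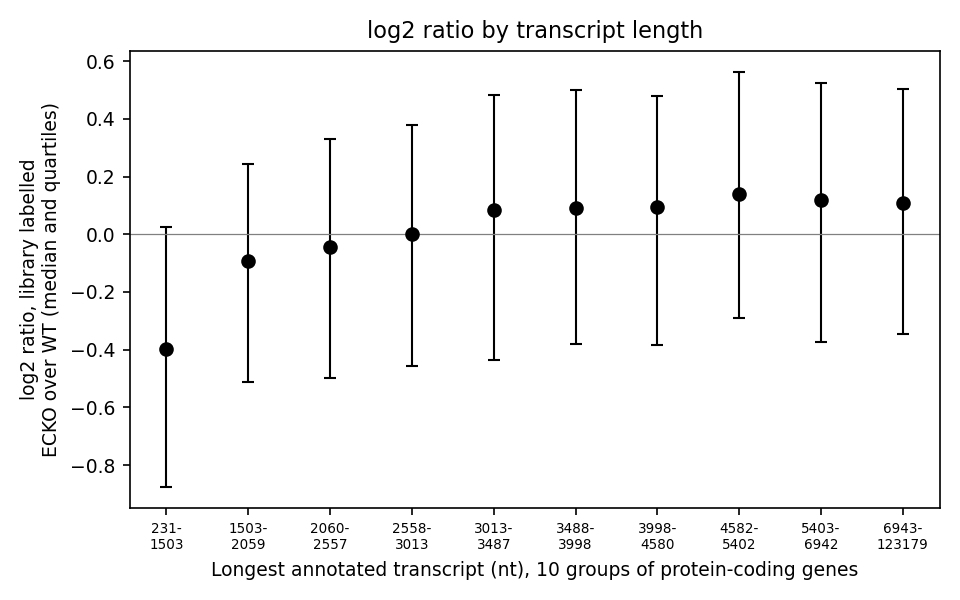
Median log2 ratio of the library labelled ECKO to that labelled WT (points, with quartiles as bars) for 10 equal groups of protein-coding genes by the longest annotated transcript in nt. The group with the shortest transcripts has a median of -0.40 and that with the longest 0.11.

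Markers of several other cell types were lower in the library labelled ECKO. Of 18 neural precursor genes, 10 were lower and none higher (median -1.25, percentile 0.01, but -0.47 over genes with a summed count of at least 200), with Olig2 at 0 against 95 counts (at least 31.3-fold). Of 23 neuron genes, 10 were lower, including Dlx1 (5.56-fold) and Ina (3.59-fold), and 2 higher, Nefm (49 against 1 counts, log2 5.63, interval 3.09 to 10.97) and Snap25 (3.85-fold), with a median of -0.90 (percentile 0.01, and -0.60 with no filter on counts). Of 14 megakaryocyte and platelet genes, 7 were lower and none higher (median -1.15, percentile 0), among them the glycoprotein Gp5 (3.53-fold). Of 26 microglia, macrophage and leukocyte genes, 11 were lower and none higher (median -0.47, percentile 0, and -0.23 with the length trend removed), led by the complement gene C1qc (1412 against 10884 counts, 7.61-fold) and the myeloid enzyme Mpo (9.64-fold). Chosen after the data were seen, the 10 of these genes with a summed count of at least 5000 had a median of -0.079 (bootstrap interval -0.24 to 0.28), and C1qa (0.16) and C1qb (-0.28) did not follow C1qc.

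Other cell type lists did not stand apart between the libraries labelled ECKO and WT. Pericyte and smooth muscle markers had a median of 0.30 (percentile 90.5, 15 genes), with Tbx18 3.41-fold higher and Acta2 lower. Fibroblast and meningeal markers had a median of 0.14 (percentile 81.5, 16 genes), with 4 genes lower, led by Dcn and Foxd1 (6.25-fold). Erythroid markers had a median of -0.03 (percentile 42.2, 18 genes), with the heme synthesis gene Alas2 2.43-fold higher, Hba-a2 3.81-fold higher but uncertain because of its identical copy, and Gata1 2.12-fold lower. Muscle and cartilage markers had a median of 0.17 (percentile 80.1, 8 genes), with Col2a1 2.89-fold higher and Mylpf 4.68-fold lower. The single tested choroid plexus and epithelial marker, the water channel Aqp1, had 0 against 83 counts, and no Hox gene reached a summed count of 50. Of the 28 lists with a percentile, including the sex-linked one, 7 lay below the middle 95% of random lists and 1 above. When matched on the longest or the principal transcript as well, 6 and 7 lay outside it. If genes varied independently, 1.4 lists would lie outside. Genes of 1 list can vary together between any 2 libraries, and several lists share genes, so the excess is no test against chance.

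**Figure D3:**
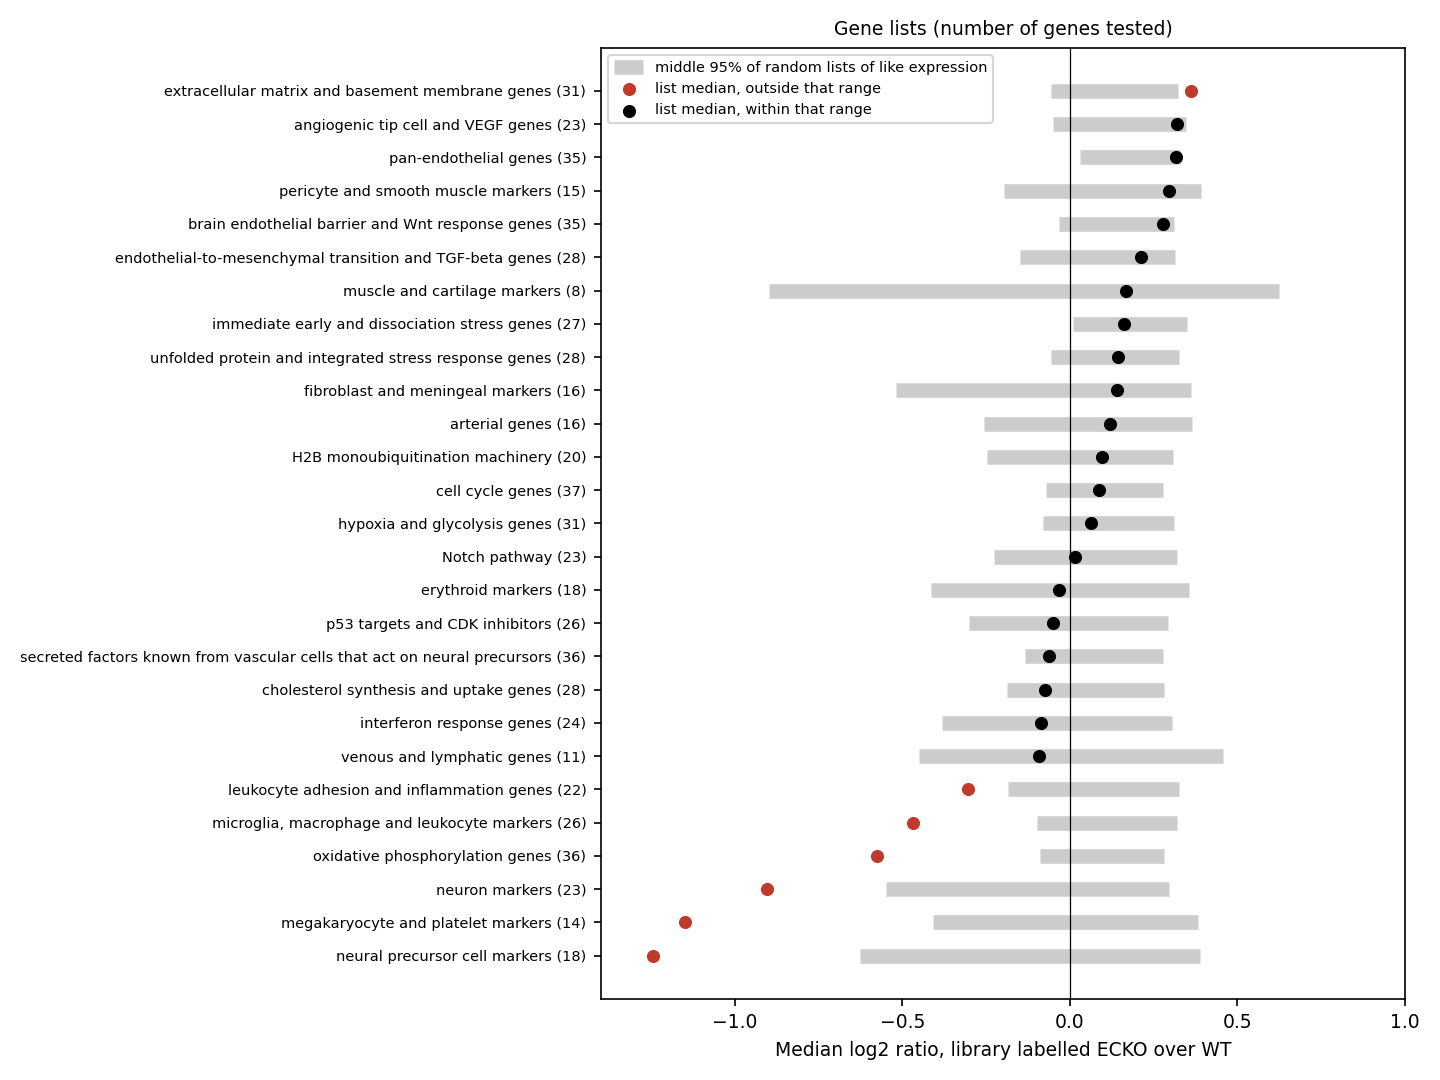
Median log2 ratio of the library labelled ECKO to that labelled WT for each gene list (points, with the number of tested genes) and the middle 95% of 10000 random lists of like expression (grey bars). Neural precursor (-1.25), megakaryocyte (-1.15), neuron (-0.90), oxidative phosphorylation (-0.58), macrophage (-0.47) and inflammation (-0.30) genes lie below their bars and matrix genes (0.36) above; the sex-linked list is not drawn.

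Genes that mark embryo sex differed between the libraries. Xist, the RNA that coats the inactive X chromosome, had 2522 counts in the library labelled ECKO and 0 in the library labelled WT (at least 851-fold higher). The Y-linked genes Ddx3y (2965 counts), Eif2s3y (1374), Uty (365) and Kdm5d (258) were found in the library labelled WT and were at 0 in the library labelled ECKO. Genotype and embryo sex therefore cannot be separated for any gene in this comparison.

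The authors' deposited table marks 1261 genes as higher and 1524 as lower in ECKO. Every gene marked in the authors' deposited table had an absolute log2 fold change of at least 2.00 and a p-value of at most 0.00092. Of these 2785 genes, 876 also passed the size rule in the same direction and 1909 had a summed count under 50. The authors' deposited table gives Rnf20 a log2 fold change of 0.23 and does not mark it.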

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

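The length-trend removal, the summed count of at least 5000 and the omission of the sex chromosomes were chosen after the data had been seen, and all other settings before. Directions are of the library labelled ECKO against that labelled WT. Against 1099 higher and 1701 lower genes, counts moved by over 1.5 times with no filter on counts (2851 and 3207), a summed count of at least 200 (534 and 841), a 1.5-fold threshold (2343 and 2934), intervals wholly beyond 2-fold (622 and 986), the authors' CPM with a pseudocount of 0.1 (1657 and 2850) and a summed count of at least 5000 (7 and 23). Apart from the CPM, these changes follow from the settings themselves, which admit more or fewer genes. The cause of the change with the CPM was not tested. Other settings stayed within 1.5 times, with 908 to 1279 higher and 1567 to 2199 lower genes. With the length trend removed, 2451 of the 2800 genes passed in the same direction.

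Scaling to total gene counts shifted every log2 ratio by -0.11. It turned Leo1, whose interval includes 0, from 0.074 to -0.036. It left the interval for 36 of 126 named genes, without a change of sign, and ended 7 of 108 calls among them, all higher and all with a log2 ratio just above 1 (Fosb, Col18a1, Rai14, Clip1, Cdkn1b, Gapdh and Rsad2, at 0.90 to 0.98). The 2 further scalings left no interval for any of them, and the upper quartile ended 1 call, Cox4i1 (-1.01 to -0.996). Of 36 oxidative phosphorylation genes, 7 in the main analysis and 5 to 10 over the other scalings were lower. Scaling to total gene counts also added lower genes to other lists: neuron 10 to 12, neural precursor 10 to 11, macrophage 11 to 12, megakaryocyte 7 to 8, immediate early 1 to 2, and pan-endothelial and tip cell 1 to 2 each. Rnf20 stayed above 0 throughout (0.23 to 0.35 over scalings) and was 0.23 with the authors' CPM and a pseudocount of 1, just outside its interval. All 28 list medians stayed within their bootstrap intervals in the 196 recalculations, but some of these intervals are wide. The median of 8 lists changed sign in 16 of them, all inside the middle 95% of random lists, as with no filter on counts (fibroblast 0.14 to -0.22), at a summed count of at least 200 (muscle and cartilage 0.17 to -0.19, p53 -0.05 to 0.17) and with total gene counts (H2B 0.10 to -0.01, Notch 0.01 to -0.09). Among lists outside it, medians moved by over 1.5 times with the length trend removed (inflammation -0.30 to -0.11, oxidative phosphorylation -0.58 to -0.28, macrophage -0.47 to -0.23), at a summed count of at least 200 (neural precursor -1.25 to -0.47), with no filter (neuron -0.90 to -0.60, macrophage to -0.74) and with the CPM and a pseudocount of 1 (sex-linked -6.91 to -4.53). No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth limits genes at 0 in 1 library, whose ratios are bounds.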

Other observations

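The gene families, single genes and count threshold in this paragraph and the next were chosen after their values had been seen, and directions are of the library labelled ECKO against that labelled WT. Ribosomal protein genes, which build the cytosolic ribosome and have short transcripts, had a median log2 ratio of -0.65 over 74 genes, with 16 lower and 1 higher (24 and 0 when scaled to total gene counts), and -0.36 with the length trend removed. Mitochondrial ribosomal protein genes had a median of -0.38 over 76 genes, and mitochondrially encoded genes a median of -0.51 over 12, which became -0.13 and -0.20 with the length trend removed. Against random lists matched on the longest or the principal transcript as well as expression, the mitochondrially encoded genes lay at percentiles 3.08 and 2.89, inside the middle 95%, whereas the ribosomal protein genes lay at 0 and 0.02 and the mitochondrial ribosomal protein genes at 0.52 and 1.64, below it. Mast cell genes were lower for the proteases Tpsb2 (0 against 220 counts), Cma1 (1 against 175) and Cpa3 (249 against 842), which were the 3 that passed the size rule among 10 genes, none being higher. The median was -0.69 (bootstrap interval -3.49 to 0.25), with 6 genes below 0 and 4 above. The complement genes C1qa, C1qb and C1qc, whose products form 1 protein complex, moved apart, with log2 ratios of 0.16, -0.28 and -2.93.

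At a summed count of at least 5000, 7 genes were higher and 23 lower. The higher ones were the actin-binding Lasp1 (2.61-fold), the caveolar Ehd2 (2.33-fold), Emp1 (2.28-fold), Clip1, Col18a1, Rai14 and Fosb, of which the last 4 did not pass when scaled to total gene counts (log2 0.94, 0.92, 0.92 and 0.91). Those lower by the most, after C1qc, were Rnf187 (6.59-fold) and Marcksl1 (6.14-fold), and the GTPase Rac1 was 4.90-fold and the linker histone H1f0 4.38-fold lower. Of X-linked genes known to escape X inactivation, Eif2s3x (2.12-fold) and Kdm5c (2.07-fold) were higher, and Kdm6a (1.45-fold) and Ddx3x (1.20-fold) did not pass the size rule. The calls of Eif2s3x and Kdm5c depend on the scaling. In the authors' deposited values, scaled to library totals, their log2 fold changes were 0.98 and 0.94, under the limit of 1. The 351 X-linked genes with a summed count of at least 200 had a median of 0.16 against 0.03 for 10059 autosomal genes.

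Of the tests in the next 3 paragraphs, only the match on longest transcripts was set before its result was seen, though the unmatched median and the length trend were already known. All other tests there were chosen after the result was seen. Genotype and embryo sex stay open as biological explanations for each pattern, since each is confounded with the 1 library.

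Rnf20 was not lower in the library labelled ECKO. A larger share of RNA from non-endothelial cells would lower endothelial genes. The pan-endothelial median was 0.32 (bootstrap interval 0.13 to 0.41), which gives no sign of a larger share but does not exclude it. That median lay at percentile 96.2 of random lists of like expression, inside their middle 95%. The middle value of those lists, 0.19, lies inside the bootstrap interval. The pan-endothelial median cannot speak to endothelial cells that kept Rnf20, because these would not lower endothelial genes. Nor can it speak to non-endothelial RNA at a like share in both libraries. Reads from exons outside the deleted part, and an exchange of the 2 labels, cannot be told apart. Rnf20 lay at percentile 73.3 of genes of like summed count, which decides neither, because the counts cover the whole gene and the labels do not say whether the deletion lowers the transcript.

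Oxidative phosphorylation genes were lower, as were short transcripts in general. Over all protein-coding genes, medians differed by 0.15 between the 10% lowest and highest in GC content. They differed by 0.51 between the 10% shortest and longest in transcript length. The trend with GC content was thus the smaller, but no random lists matched on GC content were drawn, so it was not excluded for this list. The values argue against transcript length, as matched in bins, as the whole cause. Differences in length within a bin were not matched. The list lay at percentile 0 of random lists matched on the longest transcript and at percentile 0.09 of those matched on the principal transcript, where a percentile under 2.5 had been set, for the longest transcript beforehand, as speaking against it. The matched medians were -0.10 and -0.21, against a list median of -0.58 (bootstrap interval -0.78 to -0.12), so the interval leaves out the first and includes the second. Length may account for part of the difference, since the median was -0.28 with the length trend removed. Ribosomal protein genes (median -0.65) and mitochondrial ribosomal protein genes (-0.38) also lay below random lists matched on either length. Mitochondrially encoded genes did not. The lower level is thus not particular to oxidative phosphorylation genes.

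Markers of neural, megakaryocytic and macrophage cells were lower. A smaller share of macrophages would lower their abundant transcripts together. The 10 markers with a summed count of at least 5000 had a median of -0.079 (bootstrap interval -0.24 to 0.28). Among them Csf1r was at 0.40 and P2ry12 at -0.07, but C1qc at -2.93. These values argue against a joint fall of the abundant markers to a log2 ratio of -0.5. A slightly smaller share is not excluded, and of all 26 markers 11 were lower and none higher. Whether neural or megakaryocyte-lineage cells were fewer in the library labelled ECKO stays open. The same kind of test on the 10 markers with the highest summed counts gave medians of -0.70 (bootstrap interval -1.10 to -0.21) for the neural precursor and neuron genes and -1.18 (interval -1.71 to -0.14) for the megakaryocyte genes, each with 8 of 10 below 0. Both intervals reach from below to above the bound of -0.5 used for each cell type, and these markers had as few as 577 and 500 counts, so fewer such cells and a difference in these genes cannot be told apart. The neural precursor median was -1.25, and -0.47 at a summed count of at least 200. No sort or gate is named that would remove either cell type.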
